A study of Chironomus tentans with 15 samples.

How the data were processed

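Gene expression was measured in whole fourth-instar larvae of the aquatic midge Chironomus tentans with a custom 1-colour Agilent oligonucleotide array. Per the labels' protocols, 15 larvae were placed in each glass beaker of reconstituted water at 25 °C, and 5 living larvae per beaker were pooled after 48 h as 1 sample. The beakers received acetone, the solvent control, or chlorpyrifos at 0.1 or 0.5 µg/L, or atrazine at 1000 µg/L. Samples were assigned to 4 groups by their titles, giving 3 solvent control arrays and 4 arrays in each exposed group. Replicates were taken as separate beakers, so p-values measure the spread between pools of larvae from different beakers, pooled over all groups. The median SD of a probe was 0.433 in the control group, against 0.250 to 0.381 in the exposed groups. P-values against control may therefore understate the spread of the controls.

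Per the file headers, the authors made the intensity values of the scanner files with Agilent Feature Extraction 9.5.3.1 from a Cy3 scan, with background subtraction, spatial detrending within the array and surrogate values for spots near background. These intensities were deposited on a linear scale, not normalised between arrays, and the submitters' processing notes name Feature Extraction 9.5. A table of log2 values for the same arrays was also deposited, and its scaling was found by setting each column against the scanner signal of its array. Each deposited log2 column equalled log2 of the processed signal minus 1 constant per array, within 1.8e-06, so no centring of probes had been applied and the direction of all values is that of signal. The deposited columns had their 75th percentile between 0.0036 and 0.0095, which places each constant at that percentile. Their medians per array lay between -3.74 and -3.37.

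The array holds 13674 probes of 60 bases, all with the description Unknown. No gene name is paired with any probe in the files used here, no genome was used, and probes are therefore given by their array identifier and sequence, without coordinates. For the same reason the 24 gene lists fixed before the data were examined, among them cytochromes P450, glutathione S-transferases, esterases, heat shock proteins, haemoglobins, muscle, salivary gland and fat body markers, were not tested, and acetylcholinesterase is not reported. As a replacement, 13 protein sequence motifs were searched in the 3 forward reading frames of the probes before any comparison was computed (Biopython 1.88, Python 3.11.15, pandas 2.3.3), with patterns that were not checked against a motif collection. The motif sets large enough for a set test were tested with camera (limma) at its preset inter-gene correlation of 0.01 and again with an estimated correlation.

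The main values were log2 of the processed signal minus the 75th percentile of each array. Spots with an outlier flag, 1.39% of the values of tested probes, were left out. Probes were tested when well above background on every array of at least 1 group, and 165 probes that met this but had a group with every spot marked as an outlier were left out. This left 8488 probes, 62.1% of those printed. limma 3.58.1 in R 4.3.3 fitted the 4 group means in 1 model (lmFit, eBayes), so that all groups shared 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were each pesticide group minus the solvent control, the higher minus the lower chlorpyrifos concentration, and atrazine minus chlorpyrifos at 0.5 µg/L.

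Before averaging, all 105 pairs of arrays were compared over 6665 probes that were well above background, unsaturated and unflagged on all arrays. Control arrays 2 and 3 differed by a robust SD of 0.147 on the log2 scale, while probes with identical sequence, 13 to 17 pairs per array, differed within an array by a robust SD of 0.0742 to 0.274. The next closest pair of arrays differed by 0.286. The difference of control arrays 2 and 3 therefore lay within the range of repeated spots of the same array, and they were averaged and counted as 1 sample, which leaves 2 control samples and 14 samples in all. The design fixed at the outset had 15 separate arrays, and its counts are given beside the main ones.

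Arrays had been scanned on 2 occasions, called scan 1 and scan 2. Scan 1 holds the control and atrazine arrays and scan 2 holds both chlorpyrifos groups, and the array positions within each scan are those of 1 slide of 8 arrays. Atrazine minus control and the comparison of chlorpyrifos concentrations lie within 1 scan. In each of the other 3 comparisons scan and group cannot be told apart, and their p-values contain no spread between scans.

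The number of arrays limits the precision, and no depth in counts exists for arrays. Where a probe was not well above background on any array of a group, only a bound is given as "at least N-fold": the mean of the brighter group is set against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The named probes follow a rule also fixed at the outset. Because no probe has a gene name, at most 2 rising and 2 falling probes are named per comparison, those with the largest change past the threshold and, against the control, with all exposed samples on 1 side of all control samples. Where nothing passed, the probes with the smallest p in each direction are named as not past the threshold.

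The fit was tested on simulated arrays built from the means and spreads of the 8488 probes, with 200 probes changed. At a simulated log2 change of 2, 74% to 76% of 100 changed probes were recovered in the comparisons with 2 control samples, and 85% to 93% in the comparisons of 4 against 4 samples. At a log2 change of 1 the shares were 28% to 36% and 51% to 54%. The simulation gave all samples the same spread of a probe and drew noise independently. The shares thus leave out the larger spread of the controls and any variation that many probes share.

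Alternatives fixed at the outset were normexp background correction with an offset of 50, quantile and median scaling, no filter on dim probes, only probes well above background on all arrays, the deposited log2 values, the replicate number as a block, the scan as a block, only the 2 groups compared, array weights, a trended and robust prior, each replicate left out, and 2 other thresholds. Alternatives added after the data had been seen were the 15 separate arrays, outlier spots kept, control 1 alone, the samples that stand apart left out, means of probes sharing 20 or more bases, the samples of 1 scan alone, a covariate for the spread between beakers, the replicate block with 15 arrays, 1 control sample given to each of 2 comparisons, and removal of each array's joint trend over its rows and mean signal. Other splits of the samples numbered 15 for 2 against 4 samples and 35 for 4 against 4.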

Results

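Expression was compared among C. tentans larvae kept for 48 h with acetone alone, with the organophosphate insecticide chlorpyrifos, an inhibitor of acetylcholinesterase, at 0.1 or 0.5 µg/L, or with the triazine herbicide atrazine, an inhibitor of photosynthesis in plants, at 1000 µg/L. Each array measured 1 pool of 5 whole larvae from 1 beaker. The 75th percentile of the processed signal lay between 642 and 1310 intensity units on the 15 arrays. Between 59.6% and 67.6% of the 13674 probes were well above background on an array, and 3399 probes, 24.9%, were well above background on none.

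The arrays did not fall apart by exposure alone. The leading principal component held 50.5% of the variance of the 15 arrays, and its scores were -78.3 and -78.5 for control arrays 2 and 3 and -4.41 for control array 1. Atrazine replicate 4 scored -36.2 on it, while the other atrazine arrays scored 27.5 to 33.1. Control arrays 2 and 3 differed by a robust SD of 0.147, within the range of repeated spots of 1 array, and were counted as 1 sample, so the control group has 2 samples. Those 2 samples differed by over 4-fold on 334 of the 8336 probes measured in both. The next component, with 10.8% of the variance, was above 0 on all 7 arrays of scan 1 and below 0 on all 8 arrays of scan 2.

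**Figure D1:**
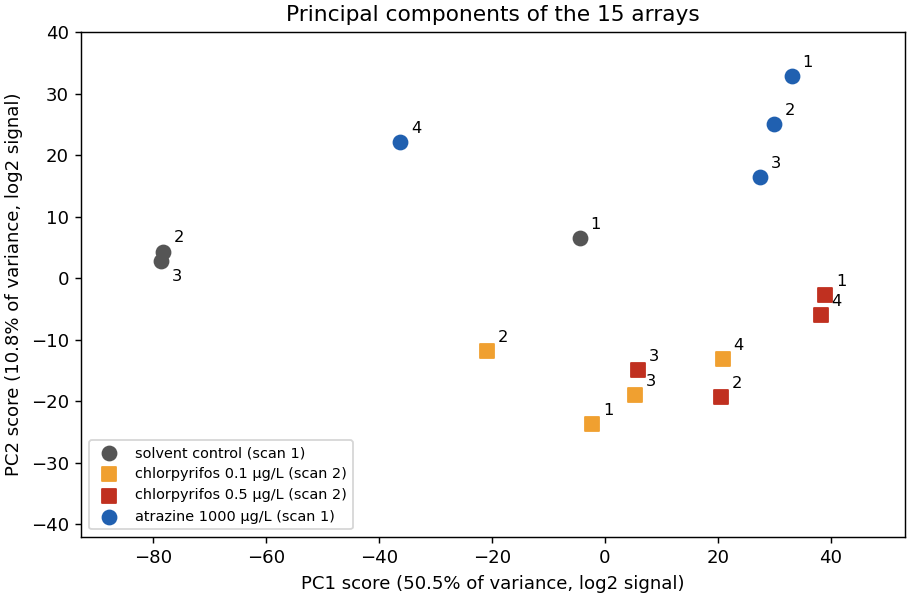
Scores of the 15 arrays on the 2 leading principal components of the log2 signal, with 50.5% and 10.8% of the variance on the axes; colours are groups, circles are scan 1, squares are scan 2 and digits are replicate numbers. Control arrays 2 and 3 lie together at -78.3 and -78.5 on the horizontal axis, and both chlorpyrifos groups overlap.

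The comparison of chlorpyrifos at 0.1 µg/L with the solvent control asked which transcripts differ at the lower concentration. Of 8488 probes, 20 were higher and 48 were lower, 68 in all (limma, adjusted p under 0.05). Among the called probes that rose were Midge 3621 and Midge 1598, neither well above background on any control array, so that their folds are given as bounds, computed with background subtracted. Midge 3621 (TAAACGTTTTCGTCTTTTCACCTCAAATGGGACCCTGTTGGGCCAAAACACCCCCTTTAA) rose from -8.49 ± 0.09 (SD, n = 2) to -5.45 ± 0.40 (SD, n = 4) in log2 signal, at least 2.10-fold, with an adjusted p of 0.00424. Midge 1598 (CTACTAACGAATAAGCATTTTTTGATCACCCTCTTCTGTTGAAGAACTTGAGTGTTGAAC) rose at least 5.39-fold with an adjusted p of 0.00152. Among the called probes that fell were Midge 3622 (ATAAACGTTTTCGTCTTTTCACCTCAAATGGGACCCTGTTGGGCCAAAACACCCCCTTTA), at least 3.54-fold lower with an adjusted p of 0.0104, and Midge 7401 (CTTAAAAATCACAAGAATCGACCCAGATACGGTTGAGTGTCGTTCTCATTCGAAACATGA), which fell by 3.13 ± 0.61 (SE) on the log2 scale with an adjusted p of 0.0300 and was well above background on 1 of the 4 exposed arrays. With normexp background correction the log2 differences of Midge 3621, Midge 1598, Midge 3622 and Midge 7401 were 0.28, 0.78, -0.89 and -1.25, none past the threshold, and of 32 alternatives these probes passed in 27, 30, 25 and 23. Midge 3622, which fell, shares 59 consecutive bases with Midge 3621, which rose, and 2 more probes that share 43 and 42 bases with Midge 3621 had log2 differences of -0.08 and -0.19. Averaged with these overlapping probes, Midge 3621 had a log2 difference of -0.14 (adjusted p = 0.838, in a range of 0.00105 to 0.838 over its 32 alternatives). Because nearly the same sequence moved in opposite directions, neither Midge 3621 nor Midge 3622 shows a change of a transcript. A probe that shares 30 bases with Midge 1598 had a log2 difference of 0.94, against a bound of 2.43 on the log2 scale for Midge 1598. All 68 called probes separated the 2 groups without overlap, as did 1862 of the 8488 probes (21.9%), where chance gives 13.3%. Of the 48 lower probes, 42 lay in array rows 1 to 96 of the 192 rows, which held 4280 of the tested probes (two-sided Fisher's exact test, adjusted p = 3.92e-07), and only 2 of the 20 higher probes did (adjusted p = 0.000261). With control arrays 2 and 3 as separate samples the count was 345, with 164 higher and 181 lower. After removal of a trend over array rows and signal it was 24, with 13 higher and 11 lower. With only the 2 groups in the fit it was 0. Scan and exposure cannot be told apart here.

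Chlorpyrifos at 0.5 µg/L was compared with the same control for the response at the higher concentration. The test called 252 probes, 136 higher and 116 lower. Among them were 64 of the 68 probes called at 0.1 µg/L, with the same direction. Both lists rest on the same 2 control samples and on exposed arrays of scan 2, so part of this overlap is shared by design. Midge 3169 (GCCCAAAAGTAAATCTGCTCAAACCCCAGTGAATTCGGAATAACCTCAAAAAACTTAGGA) rose by 3.39 ± 0.80 (SE) on the log2 scale with an adjusted p of 0.0437, against control samples with an SD of 2.03 (n = 2) of which 1 of 3 arrays was well above background. Midge 3621 had higher signal again, at least 2.46-fold with background subtracted and an adjusted p of 0.00216. Its log2 difference was 0.30 with normexp (adjusted p = 0.381) and 0.21 as a mean with overlapping probes (adjusted p = 0.664), both under that bound. It passed in 29 of 32 alternatives. Midge 3622, which shares 59 bases with it, had a fitted log2 difference of -2.95 (limma, adjusted p = 0.0166). Midge 3622 was well above background on 0 of the 4 exposed arrays. Here too, the opposite moves do not show a change of a transcript. Midge 11397 (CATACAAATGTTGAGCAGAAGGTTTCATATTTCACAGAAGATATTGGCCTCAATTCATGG) fell by 7.24 ± 1.79 (SE), from -0.16 ± 0.45 (SD, n = 2) to -7.39 ± 2.83 (SD, n = 4), with an adjusted p of 0.0494, and 1 of the 4 exposed arrays was well above background for it. Of 32 alternatives, Midge 3169 passed in 15 and Midge 11397 in 14. With normexp their log2 differences were 0.92 (limma, adjusted p = 0.137) and -3.69 (adjusted p = 0.0196). A probe that shares 30 bases with Midge 3169 had a log2 difference of 0.67. Midge 2225 (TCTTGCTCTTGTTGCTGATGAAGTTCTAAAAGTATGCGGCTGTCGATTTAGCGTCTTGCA) was at least 2.58-fold lower with background subtracted and an adjusted p of 0.00137, and passed in 31 of 32 alternatives. With normexp its log2 difference was -0.76, under that bound and not past the threshold (adjusted p = 0.0664). Of the 116 lower probes, 84 lay in array rows 1 to 96 (two-sided Fisher's exact test, adjusted p = 3.70e-06), against 47 of the 136 higher ones (adjusted p = 0.000261). All 252 called probes separated the groups without overlap, as did 3216 of the 8488 probes, 37.9%, against a chance share of 13.3%. The split of calls was 70 higher and 33 lower with median scaling and 87 higher and 48 lower with quantile normalization, and lower probes were the larger part with normexp, 217 higher and 334 lower, without a filter, 52 higher and 81 lower, and with replicate as a block, 17 higher and 29 lower. The count was 2791 with 15 separate arrays and 32 without chlorpyrifos 0.5 µg/L replicate 4. It was 89, with 64 higher and 25 lower, after removal of a trend over array rows and signal. With only the 2 groups in the fit it was 26, and with array weights 13. Scan and exposure cannot be told apart.

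**Figure D2:**
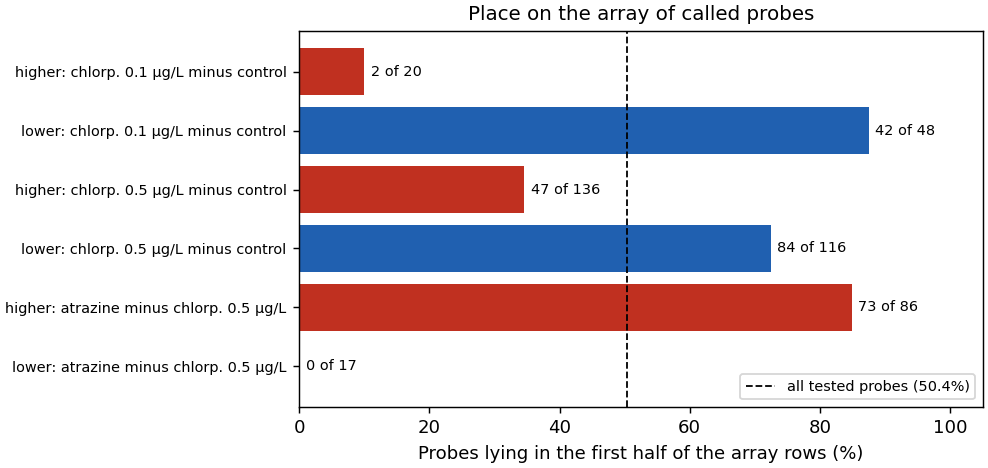
Percentage of called probes that lie in array rows 1 to 96 of 192, for higher probes in red and lower probes in blue, in the 3 comparisons across scans; the dashed line at 50.4% is the share of all tested probes. Probes lower with chlorpyrifos than with control or atrazine lie mostly in these rows, as 42 of 48, 84 of 116 and 73 of 86 did.

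Atrazine at 1000 µg/L was compared with the solvent control of the same scan. Of 8488 probes, 1 rose and 2 fell. Midge 5677 (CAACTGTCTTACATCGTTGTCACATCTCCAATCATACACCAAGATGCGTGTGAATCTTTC) rose by 2.36 ± 0.34 (SE) on the log2 scale, 5.12-fold, with an adjusted p of 0.0289, and a probe that shares 20 bases with it had a log2 difference of 0.61. Midge 13602 (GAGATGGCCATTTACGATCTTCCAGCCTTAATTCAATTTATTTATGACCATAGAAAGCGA) fell by 1.34 ± 0.17 (SE), 2.54-fold, from -1.41 ± 0.14 (SD, n = 2) to -2.75 ± 0.17 (SD, n = 4), with an adjusted p of 0.0208. Midge 13605 (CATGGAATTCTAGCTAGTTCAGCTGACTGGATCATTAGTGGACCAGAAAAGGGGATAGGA) fell by 1.21 ± 0.17 (SE), 2.32-fold, with an adjusted p of 0.0289. All 3 probes were well above background on every control and atrazine array. They were also among 1679 probes, 19.8%, on which the 2 groups did not overlap, where chance gives 13.3%. An unadjusted p under 0.05 was reached by 1964 probes, 23.1%. The count was 1791 with 15 separate arrays (932 higher and 859 lower) and 1267 without atrazine replicate 4 (561 and 706). It was 0 with only the arrays of scan 1. With scan as a block it was 3, a fit that equals the main one by construction, because the groups fix the scan. Midge 13602 stayed past the threshold in 23 of 35 alternatives, with adjusted p values from 0.00246 to 0.374, Midge 5677 in 16 and Midge 13605 in 15. With normexp, Midge 5677, Midge 13602 and Midge 13605 had log2 differences of 1.40, -0.85 and -0.68. None of them passed there (limma, adjusted p = 0.0695, 0.0879 and 0.131).

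**Figure D3:**
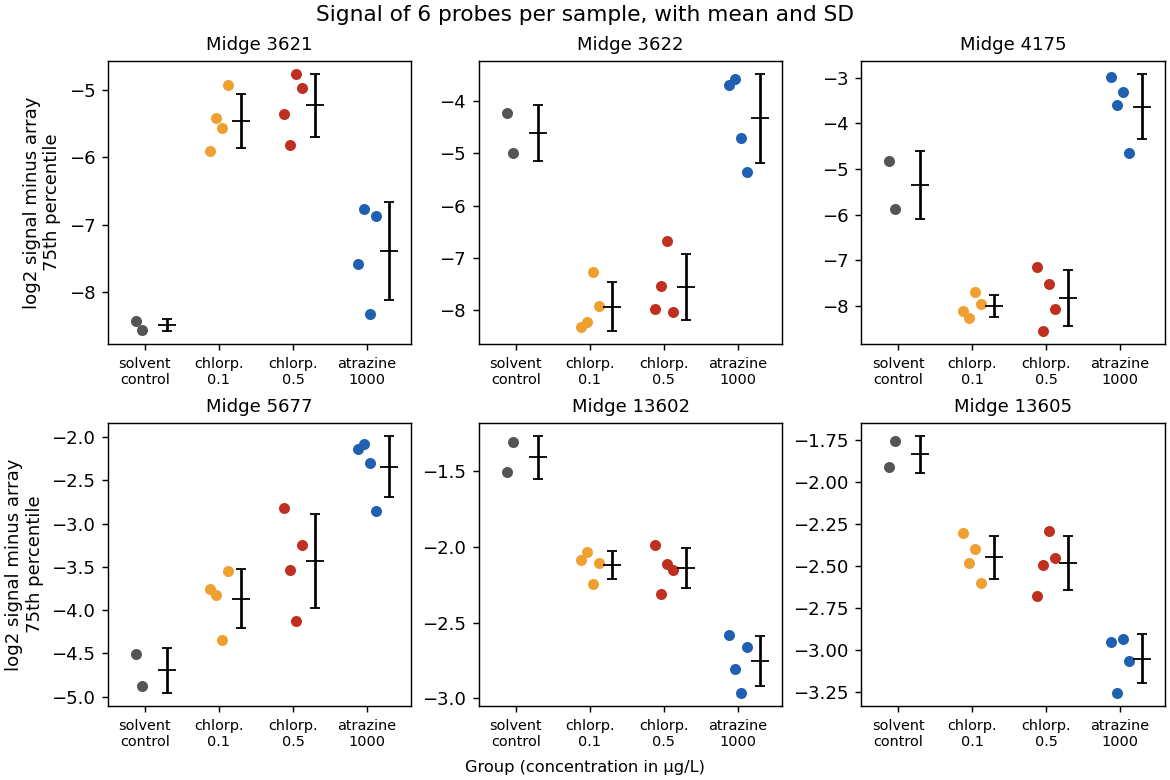
Log2 signal minus the array's 75th percentile for 6 probes, with 1 point per sample (2 control samples and 4 in each exposed group) and the mean with its SD beside the points. Midge 3621 and Midge 3622, which share 59 bases, moved in opposite directions with chlorpyrifos, and the 4 atrazine samples lie below all other samples for Midge 13602 and Midge 13605.

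The 2 chlorpyrifos concentrations were compared directly within scan 2. No probe passed (limma), 285 of 8488 (3.36%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.943. The 95% confidence interval of a difference had a median width of ± 0.55 on the log2 scale. The probes with the smallest p, none past the threshold, were Midge 5965 at 0.78 ± 0.23 (SE) and Midge 13510 at 0.81 ± 0.24 (SE) in the upward direction, and Midge 9466 at -1.09 ± 0.28 (SE) and Midge 6836 at -1.45 ± 0.38 (SE) in the downward direction, all with an adjusted p of 0.943. The 4 samples of 1 concentration lay apart from those of the other on 358 probes, 4.22%, where chance gives 2.86%.

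Atrazine at 1000 µg/L was compared with chlorpyrifos at 0.5 µg/L for a difference between the pesticides, whose concentrations are not matched. The test called 103 probes, 86 higher and 17 lower with atrazine. Midge 4175 (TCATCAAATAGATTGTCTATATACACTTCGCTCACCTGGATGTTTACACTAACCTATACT) was at least 6.92-fold higher (adjusted p = 9.7e-05), at -3.63 ± 0.72 (SD, n = 4) against -7.82 ± 0.62 (SD, n = 4), and Midge 3433 (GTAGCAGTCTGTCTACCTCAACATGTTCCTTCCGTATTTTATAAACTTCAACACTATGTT) was at least 3.83-fold higher (adjusted p = 0.000235). These bounds hold with background subtracted: with normexp the log2 differences were 1.37 and 1.10, below them, and both probes still passed (adjusted p = 0.00286 and 0.00634). Midge 3621 was at least 1.74-fold lower with atrazine (adjusted p = 0.00553) and Midge 5816 (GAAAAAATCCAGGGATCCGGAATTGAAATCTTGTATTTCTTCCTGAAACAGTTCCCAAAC) at least 1.51-fold lower (adjusted p = 0.0311). The log2 difference was 0.66 for Midge 3621 averaged with its overlapping probes and 0.020 for Midge 5816 with normexp background correction, both opposite in sign. With normexp that of Midge 3621 was -0.0095 (adjusted p = 0.987). Midge 3622 had a fitted log2 difference of 3.22 here, so the lower signal of Midge 3621 does not show a change of a transcript. Of the 252 probes called between chlorpyrifos at 0.5 µg/L and control, 70 were also called here with chlorpyrifos on the far side of both, 57 lower and 13 higher than control and atrazine. Both lists rest on the same 4 chlorpyrifos samples and set scan 2 against scan 1, so part of this overlap is shared by design. The 86 higher probes lay in array rows 1 to 96 in 73 cases (two-sided Fisher's exact test, adjusted p = 1.99e-10), and none of the 17 lower probes did (adjusted p = 1.3e-05). Probes outside the called set that shared 20 or more bases with a called one changed by a median of 0.21, against 1.74 for their 25 called partners, in the called direction. All 103 probes separated the groups, as did 682 of 8488 (8.03%), where chance gives 2.86%. The count was 33 among probes well above background on all arrays and 260 with array weights. After removal of a trend over array rows and signal it was 58, with 45 higher and 13 lower. Scan and pesticide cannot be told apart.

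The responses to chlorpyrifos at 0.5 µg/L and to atrazine, both against the same controls, shared 1 called probe, Midge 13602, lower in both. Independent lists of these sizes would share 0.0434. Across the 8488 probes, which are not independent replicates, the log2 changes correlated with r = 0.836 and a covariance of 0.510. Unchanged groups simulated against 2 shared controls gave r = 0.666 and a covariance of 0.114 with the pooled spread, and r = 0.815 and 0.251 with the spread of the controls themselves. These simulations drew the noise of each probe independently, whereas deviations of adjacent probe numbers correlated at a mean of 0.608 in the data. The simulated values therefore do not show how far r can rise without a shared response. For chlorpyrifos at 0.1 µg/L and atrazine no called probe was shared, r was 0.745 and the covariance was 0.339. The changes at the 2 chlorpyrifos concentrations correlated with r = 0.894 and a covariance of 0.467. With 15 separate arrays, chlorpyrifos at 0.5 µg/L and atrazine shared 1384 calls, where independent lists would share 294. Control sample 1 was then given to chlorpyrifos at 0.5 µg/L and the averaged control arrays 2 and 3 to atrazine. Over 8336 probes r was 0.410 and the covariance 0.297, and the other way round r was 0.297 and the covariance 0.211. Separate controls gave r = 0.0366 and 0.234 for chlorpyrifos at 0.1 µg/L and atrazine, and r = 0.167 and 0.481 for the 2 chlorpyrifos concentrations. Each of these fits held 1 control sample, so the spread of the controls was not measured and shared calls are not compared.

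Probes that encode known protein motifs were followed as groups. Trypsin-type active-site signatures, found in digestive and other serine proteases, were present on 12 probes, and none of the 10 tested passed in any of the 5 comparisons. Their median log2 change was 0.17 with chlorpyrifos at 0.1 µg/L, 0.33 at 0.5 µg/L and 0.22 with atrazine, each against control, with an adjusted p of 0.843 in all 3 (camera, preset correlation) and 0.883 with an estimated correlation. The mean at 0.1 µg/L was -0.0049, opposite in sign to the median, and so were the mean of 0.06 and the median of -0.11 for atrazine minus chlorpyrifos. Adjusted over the list alone, 1 of these probes passed in each chlorpyrifos comparison with control and in atrazine minus chlorpyrifos. The P-loop motif of ATP- and GTP-binding proteins matched 21 probes, against 13 shuffled sequences, and of 15 tested 1 passed, in atrazine minus chlorpyrifos, where the group's adjusted p was 0.843, and 0.883 with an estimated correlation. Adjusted over the list alone, 1 P-loop probe passed there and 1 passed between chlorpyrifos at 0.5 µg/L and control. The P-loop group's adjusted p in the other 4 comparisons was 0.843 or 0.877, and the other 2 trypsin-type values were 0.843 and 0.979. The 1 probe with the haem-binding signature of cytochromes P450, the 2 with the cuticle protein core and the 3 tested with an EF-hand calcium-binding loop did not pass in any comparison, nor did single probes with a protein kinase, zinc knuckle or RNA-binding motif. No probe matched the thioredoxin, HSP70, carboxylesterase type B or ABC transporter signatures in a forward frame.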

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

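The tests on the control arrays and on the place of spots were chosen only after those results had been seen. Atrazine replicate 4 lay far from the other 3 arrays of its group on the leading principal component, at -36.2. Midge 11397 in chlorpyrifos 0.5 µg/L replicate 3, at -3.15, and in atrazine replicate 4, at -4.05, and Midge 13510 in chlorpyrifos 0.1 µg/L replicate 2, at -1.18, each lay far from the other samples of the group. These were 4 of 87 groups examined, and chance gives about 4.35. Only exposed samples were examined in this way, not the controls. The 2 pesticides differed by their direct test on 103 probes. The named ones had fitted log2 differences, atrazine minus chlorpyrifos at 0.5 µg/L, of 4.19 for Midge 4175, 3.51 for Midge 3433, -2.16 for Midge 3621 and -1.90 for Midge 5816. Each was well above background on no array of 1 of the 2 groups, so these values do not measure the size of the change. With background subtracted, the bounds were at least 6.92-fold and 3.83-fold higher and at least 1.74-fold and 1.51-fold lower.

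Control arrays 2 and 3 stood apart from control array 1. The brightness of the arrays is argued against, since 8 other arrays had a 75th percentile of signal between those of these 2. Their difference of 0.147 (robust SD) lay within the range of identical spots on 1 array, which is consistent with 2 hybridisations of 1 RNA sample, although the labels list them as separate samples. Across probes, the difference between the 2 control samples correlated at 0.672 in size with the main axis along which exposed samples of the same group differ, so a difference between beakers that also occurs among exposed beakers, may add to the contrast with control. Repeated spots of spiked-in control probes had an SD of 0.538 (log2) on control array 1, against 0.116 to 0.200 on the other arrays. Its identical-sequence spots differed by a robust SD of 0.167, within the range of the other arrays. Whether the quality of control array 1 adds to the difference was not tested. The labels used here give the larval instar but no measure that differs between beakers of 1 group, and no biological explanation was tested.

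The probes brighter with atrazine than with chlorpyrifos at 0.5 µg/L numbered 86, with a median log2 difference of 1.81. A general offset of that size on the chlorpyrifos scan at low signal is argued against. The 50 uncalled probes nearest to each in signal on the atrazine arrays differed by a median of 0.0182. They were not matched on the chlorpyrifos arrays, so a smaller offset among probes dim there stays open. Without the filter on dim probes, the median over all 13509 probes was 0.143, against 0.0213 with it. A defect of single spots or probes on the slide of 1 scan may contribute. Overlapping probes outside the set differed by a median of only 0.174, against 1.84 for the 20 members with such a partner. Such partners were uncalled by definition, which lowers their median, so this contrast alone does not show a defect. For the 103 probes with the smallest p for atrazine minus control, overlapping probes kept 83.1% of the change. Overlapping probes kept 80.6% of the change of their 203 called partners between atrazine and control, within scan 1 with 15 separate arrays, but across the scans they also kept 60.7% for chlorpyrifos at 0.5 µg/L minus control, with 49 of 54 in the same direction, and 26.3% at 0.1 µg/L, so such defects would not cover all calls across scans. The place of the spots on the array may also contribute, since 84.9% of the set lay in array rows 1 to 96, against 50.4% of all tested probes. Of the 17 probes lower with atrazine, 0 lay there. Probe number was unrelated to array row (Spearman correlation of -0.0031). An effect of chlorpyrifos on transcripts alone is therefore argued against for the set, since it would not sort probes by row. An effect on part of the set stays open, because scan and pesticide cannot be told apart. After removal of a joint trend over array rows and signal, 58 probes were still called.

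Other splits of the samples were counted for each comparison. For atrazine minus chlorpyrifos at 0.5 µg/L, only the real split, 1 of 35, gave as many as 103 probes. The highest other split gave 0. A share of 1 in 35 is under 0.05 and the smallest these splits can give, so chance is argued against but not excluded. The real split is also the split by scan, so the splits do not separate pesticide from scan. For the 2 chlorpyrifos concentrations all 35 splits, the real one included, gave 0 probes, so that with a real count of 0 the splits decide nothing. With 2 control samples there are 15 splits, too few for a share under 0.05. There the real split gave 68 probes at 0.1 µg/L against a highest other of 0, 252 at 0.5 µg/L against 1, and 3 with atrazine against 2930, with 1, 1 and 2 splits as large as the real one. The split with 2930 probes set atrazine replicate 4 together with the averaged control arrays 2 and 3, which points to a structure of the samples other than exposure.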

How the results depend on the processing

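The 15-array, control 1 alone, stand-apart, overlapping-probe, within-scan, beaker-axis, row-and-signal trend, kept outlier spot, separate-control and separate-array block alternatives were chosen after the data had been seen, and the cause of each change below was not tested unless named. Counts are given in the order chlorpyrifos 0.1 µg/L, chlorpyrifos 0.5 µg/L and atrazine, each minus control, then atrazine minus chlorpyrifos 0.5 µg/L, and last the calls shared by chlorpyrifos 0.5 µg/L and atrazine, where a value moved by over 1.5 times from 68, 252, 3, 103 and 1. Normexp gave 14, 551, 0 and, shared, 0. Quantile normalization gave 135, 1 and 0 for chlorpyrifos 0.5 µg/L, atrazine and shared calls. Median scaling gave 45, 103, 0 and shared 0, and it moved the median of all probes from -0.01 to 0.18 at 0.5 µg/L and from 0.04 to 0.17 with atrazine. No filter gave 133 at 0.5 µg/L, 0 with atrazine and 0 shared. Probes well above background on all arrays gave 19, 125 and, between pesticides, 33, with fewer probes tested (7562). Only the 2 groups compared gave 0, 26 and 0, with fewer samples for the spread. Array weights gave 3, 13, 0, 260 and shared 0. The 15 separate arrays gave 345, 2791, 1791 and shared 1384. Separate controls were control 1 for 1 pesticide and control arrays 2 and 3 for the other. Each fit then held 1 control sample, so shared calls are not compared. Control 1 alone, with its spread taken from the other groups, gave 14 and 18, and 2 shared. Leaving out atrazine 4 and chlorpyrifos 0.1 µg/L 2 gave 1237, 1331 and shared 772 for the higher concentration, atrazine and both. The beaker-axis covariate gave 53 at 0.5 µg/L and 171 between pesticides. Removing a joint trend over array rows and mean signal gave 24, 89, 1, 58 and shared 0, and rows were not removed alone. The arrays of scan 1 alone gave 0 for atrazine, with 7 arrays. An unadjusted p under 0.05 with 2-fold change gave 426, 1192, 809, 221 and, between chlorpyrifos concentrations, 75, its threshold being less strict. That last comparison gave 0 calls in every other alternative.

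Leaving out 1 replicate gave 38 to 133, 32 to 2265, 0 to 1267, 62 to 113, shared 0 to 971, and 0 to 0 between chlorpyrifos concentrations. Counts moved by over 1.5 times at 0.1 µg/L without chlorpyrifos 0.1 µg/L 1 (38) and 3 (44). At 0.5 µg/L they did so without chlorpyrifos 0.1 µg/L 1 (115) and 3 (116). They also did so there without chlorpyrifos 0.5 µg/L 1 (81), 2 (92) and 4 (32), and atrazine 1 (109), 3 (164) and 4 (1183). With atrazine they did so without chlorpyrifos 0.1 µg/L 1 (0) and 2 (1), and chlorpyrifos 0.5 µg/L 2 (1) and 4 (0). There they also did so without atrazine 1 (1), 2 (0), 3 (0) and 4 (1267). Between pesticides the count did so without chlorpyrifos 0.5 µg/L 4 (62). The shared calls numbered 709 without atrazine 4, and 2 without chlorpyrifos 0.1 µg/L 4 or chlorpyrifos 0.5 µg/L 3. They numbered 0 without control 2, chlorpyrifos 0.1 µg/L 1 or 3, chlorpyrifos 0.5 µg/L 1, 2 or 4, or atrazine 1, 2 or 3.

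Replicate numbers did not pair the samples: of 21 same-numbered pairs 8 had deviations correlated over 0.1, with r from -0.44 to 0.40. The replicate block gave 17, 46, 0 and shared 0 with control arrays 2 and 3 averaged under number 2, and 146, 2462, 1202 and shared 933 with them separate. Scan as a block gave 3 and 0 within scans and could not be fitted across them. Because the groups fix the scan, this fit equals the main one within scans by construction. For the same reason, with scan as a random block limma set the correlation within scans to 0, which leaves the fit as it was. Gene lists were not run for want of gene names, and a mean over probes of a gene likewise. Of 802 values of named or singled-out probes under alternatives, 648 kept direction and side of the threshold, 135 lost and 16 gained the call. The other 3 changed sign: Midge 3621 as a mean with overlapping probes, -0.14 at 0.1 µg/L and 0.66 between pesticides, and Midge 5816 with normexp, 0.020. The 648 include uncalled probes that stayed uncalled, such as those between the chlorpyrifos concentrations, in 35 of 35 alternatives each. They also include alternatives that could hardly differ, such as the deposited values, which differ from the main ones by 1 constant per array. The 648 therefore do not measure how stable the calls are. Signal over background limits the folds of dim probes, and 89.7%, 63.5% and 96.1% of the calls at 0.1 µg/L, at 0.5 µg/L and between pesticides lay below the median signal of the tested probes.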

Other observations

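The tests and both motif searches in this part were chosen only after the results had been seen. Midge 13602 and Midge 13605, which fell with atrazine, belong to 5 consecutive probe numbers that share no stretch of 20 bases and that all had lower signal with atrazine. Their log2 differences from control lay between -1.34 and -1.10, and those of chlorpyrifos at 0.5 µg/L between -0.73 and -0.62. The 5 were chosen as the unbroken run of numbers around Midge 13602 on which the 4 atrazine samples lay below the other 10 samples. Over all tested probes this held for 30 probes, where chance gives 8.48. The 3 other probes of the 5 did not pass the threshold with atrazine, and passed it in 5, 5 and 6 of 35 alternatives each. The 5 probes lay in array rows 20, 89, 109, 109 and 166. Correlation could not decide whether 1 transcript is read by all 5 probes. Their deviations from the group means correlated at a mean r of 0.499. Of 2542 other runs of 5 consecutive numbers without shared bases, 1270 reached this, with a median of 0.498. The reading frames of the 5 probes were not compared with protein sequences. In its forward frame 1 of the 3 other probes matched a residue pattern written for acid lipases. The pattern was written after the values had been seen and not checked against a motif collection. That probe did not pass with atrazine (adjusted p = 0.0916 from limma, 0.00744 to 0.735 over its alternatives). The pattern covers 1 block of residues, so it does not tell whether the other probes read such a protein.

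Neighbouring probe numbers in general moved together: deviations from the group means correlated at a mean of 0.608 over 5379 pairs of adjacent numbers without shared bases, against 0.00081 for random pairs. Of 847 pairs of overlapping probes, 1 per family, the log2 changes correlated across pairs at 0.899 for atrazine minus control and 0.851 between the chlorpyrifos concentrations, both within 1 scan, and at 0.727, 0.835 and 0.575 for the 3 comparisons across scans, chlorpyrifos 0.1 and 0.5 µg/L minus control and atrazine minus chlorpyrifos. The 1 probe matching a second residue pattern written for HSP70 chaperones was lower with chlorpyrifos at 0.5 µg/L than with control. Its log2 difference was -1.53 ± 0.36 (SE, adjusted p = 0.0437 from limma). It lost this call in 15 of 33 alternatives, with adjusted p values from 0.00633 to 0.498. The pattern was also written after the values had been seen and not checked against a motif collection. Between the concentrations the log2 difference of this probe was -1.04 ± 0.29 (SE, not past the threshold). It was -1.19 ± 0.36 (SE, adjusted p = 0.129 from limma) for atrazine minus control. For atrazine minus chlorpyrifos at 0.5 µg/L it was 0.34 ± 0.29 (SE, adjusted p = 0.803), so the lower signal was not shown to be particular to chlorpyrifos.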
